A study of Mus musculus with 24 samples.

How the data were processed

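RNA from flow-sorted splenic T cells of male C57BL/6 mice was counted on the nCounter Myeloid Innate Immunity Panel for mouse, which reads barcode counts without amplification. Per the labels, total RNA was extracted with a column kit (RNeasy Micro) and its quality was checked by Nanodrop and on an Agilent instrument. The deposited values are raw barcode counts per probe and sample: they are whole numbers, and neither the library totals nor the positive controls were equal between samples, so no scaling had been applied. The software version, the imaging settings and any background handling are not given in the sources used here. The table held 776 probes, of which 8 were negative controls, 6 were positive controls and 762 were endogenous. Probes were named through a table of RefSeq accessions and symbols (assembly GRCm38.p6), which matched 749 of the 762. The other 13 were kept under their identifiers, and no coordinates were used.

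Groups were taken from the sample labels (treatment and day), with 4 samples in each of 6 groups. The groups, the tests, the gene lists, the rule for the genes named and most of the alternatives were chosen before the data were examined. A probe was tested when it reached the mean plus 2 SD of the negative controls of its library in at least 4 of the 24 libraries, which kept 528 probes and left out 234. Counts were scaled by TMM factors and fitted in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood method, with all 24 libraries in 1 fit of 6 groups. The common dispersion was 0.0776, a coefficient of variation between libraries of 0.279. p-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of its F statistic, and its median was 0.23 to 0.235 for pairs of groups and 0.329 to 0.33 for the differences between changes over time. CPM values are TMM-scaled and given as mean and SD of 4 libraries.

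There were 12 comparisons: each pair of treatments at each day, the days within each treatment, and the difference in the change over time for each pair of treatments. The genes named in a comparison were the 10 largest rises and the 10 largest falls among those that passed, or all where fewer passed, or the 3 with the smallest p where none passed; up to 4 members with the smallest p of each called list; and, where tested, Vip, Vipr1, Vipr2 and 19 T cell genes. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Of 26 lists fixed in advance, 22 had at least 4 tested genes. VIP and its receptors, mast cell and basophil, erythroid, platelet and progenitor, and stroma, endothelium and matrix had 3, 3, 3 and 2 tested genes and were not tested as lists. None of the genes in the first of these passed in any comparison in the main edgeR fit. Lists share members: of the 16 tested granulocyte markers 1 is in another list, as is 1 of the 22 monocyte and macrophage markers. In each called list the median and the test had the same sign. With the correlation between genes estimated from the data, no list was called in any comparison.

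The test was run on simulated counts with the dispersions and totals of these libraries, in which 200 of 528 genes were changed in 10 runs. For VIP-KO against WT it recovered 42.7% of 1.5-fold, 70.3% of 2-fold and 90.6% of 4-fold changes at day 8, and 44.6, 71.6 and 91.2% at day 15. For WT against Control at day 15 the shares were 42.5, 69.4 and 91.2%, and for the days with WT pDC 43.9, 70.0 and 90.5%. Of the calls, 2.45 to 2.86% were false. These shares hold for many genes changed at once. A few changed genes, or background counts added to the signal, were not simulated. camera found a list shifted 2-fold in 10 of 10 runs. The simulated genes were drawn independently, so these runs do not show how camera does where genes of a list vary together.

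The alternatives were DESeq2 1.42.0 with its size factors, scaling to 19 reference genes, quantile normalization with limma, no filter on low counts, a filter of 50 counts in 12 libraries, limma on log2 values with a pseudocount of 10 (1 otherwise), limma without a variance trend, limma with sample weights, fits of only the groups compared, a block for replicate number, a fold change of at least 1.5, leaving out each library in turn, and for lists an estimated correlation and fry. After seeing the data 4 more were added: leaving out the 5 libraries under 150000 counts (called shallow), leaving out these and a 6th library in which over 75% of endogenous probes reached 20 counts, subtracting the mean of the negative controls, and a replicate block in a fit of only VIP-KO and WT at day 15. Whether replicate numbers pair samples was checked by the correlation of same-numbered libraries in their deviations from the group means. VIP-KO and WT at day 15 were the only 1 of 6 pairs of groups of a day in which all 4 correlations were above 0.1 (0.122 to 0.221, against -0.26 to 0.144 for different numbers). The labels give no source for this pairing. Counting error limits the shallow libraries most. Their counts near background turn into high CPM values once scaled, and the intervals cover only the spread between libraries.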

Results

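T cells were isolated by flow sorting from the spleens of mice in 3 treatment groups, which GEO's labels call VIP-KO pDC, WT pDC and Control, and were profiled at day 8 and at day 15. Plasmacytoid dendritic cells (pDC) are blood-borne dendritic cells that secrete type I interferon and can restrain T cells, and vasoactive intestinal peptide (VIP) is a neuropeptide with effects on immune cells. The title of the series places its interest in what VIP-expressing pDC do to T cells. Each of the 6 combinations of treatment and day held 4 samples, 24 in all. RNA was counted on the nCounter mouse panel for myeloid innate immunity, on which 528 of 762 endogenous probes rose far enough above background to be tested. The knockout lies in the pDC and not in the T cells that were measured, so Vip in these libraries does not check the labels. The labels do not say what the Control mice received, whether the replicates of a group were separate mice, or on which run a sample was read. The p-values therefore measure only the spread between these samples, which may be technical, and a run that followed the day could not be told from the day itself.

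The total endogenous count per library ran from 18250 to 1513542, an 82.9-fold range. At day 8 the totals were 34552 to 1410644 in the VIP-KO libraries, 293306 to 1321448 in WT and 95479 to 1513542 in Control. At day 15 they were 807286 to 943968 in VIP-KO, 101433 to 910219 in WT and 18250 to 940188 in Control. The libraries under 150000 counts were VIP-KO day 8 replicates 1 and 2, Control day 8 replicate 2, WT day 15 replicate 2 and Control day 15 replicate 1, 5 in all. The negative control probes averaged 9.75 to 17.1 counts per library, which corresponded to 15.0, 23.2, 11.6, 8.26 and 60.5% of the endogenous signal in those 5 libraries and to 4.06% or less in the other 19. In Control day 15 replicate 3, 165 of the 234 probes left untested reached the background limit, against 0 to 12 in the other 23 libraries. H2ac18, a histone gene, had the highest count in all 12 day 8 libraries, and the chemokine gene Ccl5 had the highest count in all 12 day 15 libraries.

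**Figure D1:**
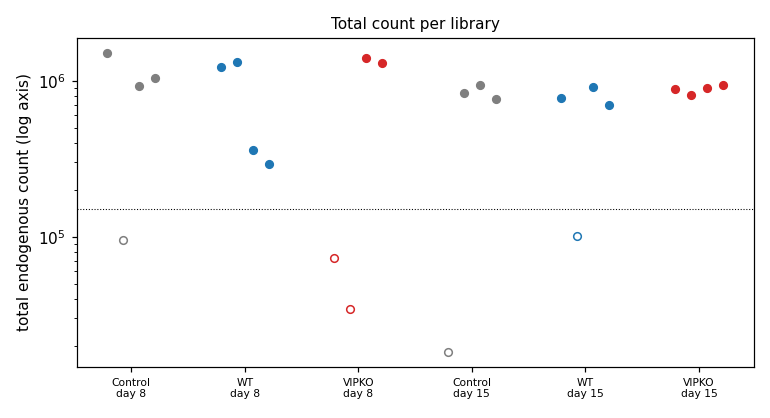
Total endogenous count per library on a log axis, by treatment and day, with 4 libraries per group; open circles mark the 5 libraries under 150000 counts (dotted line). The lowest total is 18250 in Control at day 15 and the highest is 1513542 in Control at day 8.

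The comparison of VIP-KO with WT at day 15 asks whether T cells differ with the loss of VIP from the pDC. Pdgfb, a growth factor gene, averaged 216 ± 35.6 CPM (counts scaled to a common library total; mean ± SD, n = 4) with VIP-KO pDC and 376 ± 57.4 (n = 4) with WT pDC. Spry2, an inhibitor of growth factor signalling, averaged 638 ± 97.1 against 1048 ± 212. Nfil3, a transcription factor of T cells and innate lymphocytes, averaged 739 ± 110 against 1008 ± 118. These 3 genes had the smallest p-values, with log2 fold changes of -0.78 ± 0.19 (SE) for Pdgfb, -0.72 ± 0.19 for Spry2 and -0.44 ± 0.12 for Nfil3, and did not pass the adjusted threshold (edgeR adjusted p = 0.162 for each). The cell cycle and proliferation list was higher with VIP-KO pDC in 6 of its 7 genes, with a median log2 fold change of 0.34 (camera adjusted p = 0.00347; adjusted p = 0.563 with an estimated correlation). The reference genes were higher in 14 of 19 (median 0.09) and the monocyte and macrophage markers lower in 19 of 22 (median -0.44) without passing (adjusted p = 0.0586 each). Birc5, which keeps dividing cells alive, and the mitotic genes Aurka and Ccnb2 had log2 fold changes of 0.46 ± 0.21, 0.34 ± 0.19 and 0.44 ± 0.26, and Mcm5, a replication gene, had 0.34 ± 0.20. Of the 7 members 0 passed on their own in the edgeR fit of all groups, adjusted over all genes or adjusted over the list alone.

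No gene of the 528 passed in VIP-KO against WT at day 15 with edgeR (0 called, 29 at an unadjusted p under 0.05 where chance gives 26.4). DESeq2 and limma after quantile normalization also called 0. By contrast limma with sample weights, which gives the more variable libraries less weight, called 41 genes, 19 higher and 22 lower with VIP-KO pDC, with Pdgfb at an adjusted p of 0.00459. An edgeR fit of only these 8 libraries with a replicate block, chosen after seeing the data, called 17 genes (9 higher and 8 lower). Spry2 (0.016), Pdgfb (0.0212) and Nfil3 (0.0265) were among the falls. H1f2 (0.016), Top2a of the cell cycle list and Kif20a (0.0212 each) and Pclaf (0.042) were among the rises, named after their values were seen. Neither the block in the fit of all groups nor the fit of these 8 libraries without it called any. The 4 libraries of each group did not overlap for 61 genes (11.6%, where chance gives 2.86%), Pdgfb, Spry2, Mcm5 and the cytokine gene Il10 among them. Il10 averaged 72.0 ± 14.7 CPM with VIP-KO pDC and 129 ± 31.3 with WT pDC, a log2 fold change of -0.80 ± 0.35 that did not pass (edgeR adjusted p = 0.839). In the growth factor and TGF-beta signalling list 1 gene was higher and 1 lower adjusted over the list alone, Csf1 (0.85 ± 0.25) and Pdgfb, against 0 over all genes. In simulated data of this size with 200 of 528 genes changed at once, 44.6% of 1.5-fold and 71.6% of 2-fold changes were recovered in this comparison. Changes of this size could go uncalled, and the shares for a few changed genes were not simulated. Without WT replicate 1 the count of lists fell from 1 to 0, and it was 2 without WT replicate 4 and 3 without VIP-KO replicate 4 or WT replicate 3.

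The comparison of WT with Control at day 15 asks what the WT pDC group adds to the Control state. Nfil3 was the only gene that passed. It averaged 1008 ± 118 CPM (SD, n = 4) with WT pDC and 654 ± 58.5 (n = 4) in Control, a 1.57-fold rise (log2 fold change 0.65 ± 0.12, edgeR adjusted p = 0.00881). The 4 WT libraries all lay above the 4 Control libraries. The chemokine genes Ccl3 and Ccl4, whose products attract T cells and macrophages, averaged 12403 ± 2414 against 6291 ± 2565 and 3045 ± 598 against 1469 ± 573 CPM. Their log2 fold changes of 0.96 and 0.98 did not pass (edgeR adjusted p = 0.0741 and 0.0617). Nor did those of Nr4a2, a gene induced by T cell receptor signals (0.96, 0.0617), Pdgfb (0.78, 0.0617), Rgs16, a regulator of chemokine receptor signalling (0.66, 0.0741), or Spry2 (0.67, 0.122). Emp1, a membrane protein gene, was lower at -0.85 and did not pass (0.0617). Apart from Nfil3, these genes were chosen after their values were seen.

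The call of Nfil3 was lost with reference gene normalization (adjusted p = 0.0519), quantile normalization (0.287), no filter on low counts (0.496) and a fit of only the groups compared (0.243), and without WT replicate 1 (0.0635), WT replicate 4 (0.054) or Control replicate 2 (0.0792). Its log2 fold change stayed between 0.52 and 0.81 in these settings. edgeR called 0 genes without each of those 3 libraries, 3 without WT replicate 2 and 4 without Control replicate 3 or Control replicate 4. DESeq2 called 8 genes (7 higher, 1 lower) and limma with sample weights called 25 (20 higher, 5 lower). The fit without the 5 shallow libraries, which was chosen after seeing the data, called 10. With all libraries edgeR had 36 genes at an unadjusted p under 0.05, where chance gives 26.4, and the groups did not overlap for 33 genes (6.25%, where chance gives 2.86%). Adjusted over the list alone, Ccl3 and Ccl4 passed in the Th1 list and in the chemokine ligands list (2 of 11 there). By the same measure 1 gene was higher in each of the apoptosis (the TNF receptor gene Tnfrsf1a), immediate early and cAMP response (Nr4a2) and growth factor and TGF-beta signalling (Pdgfb) lists. Pdcd1lg2, a ligand of the checkpoint receptor PD-1, was the only gene of the T cell activation and checkpoint list that was lower adjusted over the list alone. None of these passed over all genes.

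**Figure D2:**
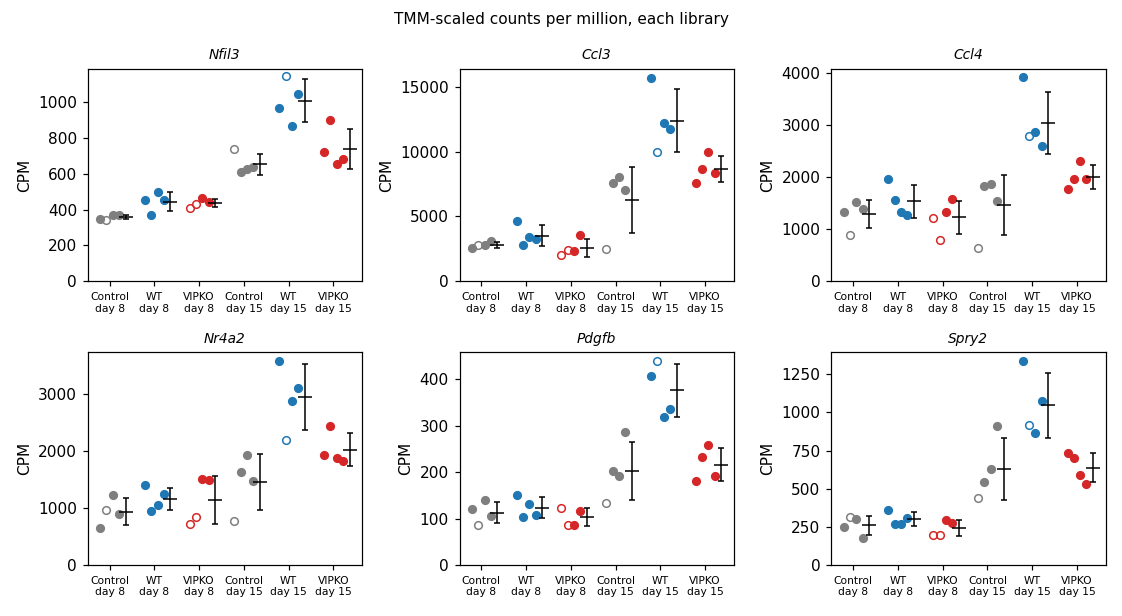
TMM-scaled counts (CPM) of Nfil3, Ccl3, Ccl4, Nr4a2, Pdgfb and Spry2 in each library by treatment and day; points are libraries (open circles: under 150000 counts) and black bars give the mean and SD of 4 libraries. At day 15 Nfil3 averages 1008 CPM with WT pDC, 739 with VIP-KO pDC and 654 in Control.

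The class I antigen presentation list was higher with WT pDC than in Control at day 15 in 10 of 12 genes (median log2 fold change 0.22, camera adjusted p = 0.035; adjusted p = 0.694 with an estimated correlation). Its members with the smallest p-values were the peptide transporter gene Tap2 (0.29 ± 0.14), the class I heavy chain genes H2-K1 (0.44 ± 0.25) and H2-T23 (0.30 ± 0.19), and H2-Q10, which went the other way (-0.37 ± 0.24). The monocyte and macrophage marker list was lower in 21 of 22 genes (median -0.58, adjusted p = 0.00951; adjusted p = 0.694 with an estimated correlation). It was led by the Fc receptor gene Fcgr1 (-1.56 ± 0.77), the adhesion gene Vcam1 (-1.13 ± 0.59), the scavenger receptor gene Cd163 (-1.48 ± 0.93) and Timd4, a receptor for dying cells (-1.86 ± 1.20). Fcgr1 and Cd163 were above background in 0 of 4 WT libraries, and without Control replicate 1, in which background made up 60.5% of the signal, 0 lists were called in place of 2. Without WT replicate 3 or WT replicate 4, 1 list was called.

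VIP-KO and Control were compared at day 15 as the third pair of treatments. Emp1 averaged 137 ± 12.9 CPM with VIP-KO pDC and 254 ± 85.2 in Control (n = 4 each). Rgs16 averaged 971 ± 39.5 against 592 ± 201, and Tnfsf10, the gene of the death ligand TRAIL, averaged 1530 ± 176 against 994 ± 294. Their log2 fold changes of -0.75, 0.61 and 0.56 did not pass (edgeR adjusted p = 0.292 for each). The Th2 list was lower in 11 of 12 genes (median -0.83, camera adjusted p = 0.0276, and 0.571 with an estimated correlation). It was led by Il10 (-0.96 ± 0.37), Ptgdr2, a prostaglandin receptor gene of Th2 cells (-2.13 ± 0.84), Ccr4 (-0.85 ± 0.41) and Il9 (-1.54 ± 0.76). For Il10 the Control mean includes 404 CPM in the shallow replicate 1, against 79.5 to 125 in the others. The cell cycle and proliferation list was higher in 7 of 7 genes (median 0.42, adjusted p = 0.0167; 0.571 with an estimated correlation), led by Birc5 (0.49), Mcm5 (0.42), the topoisomerase gene Top2a (0.59) and Ccnb2 (0.43).

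The class I list was also higher with VIP-KO pDC than in Control (10 of 12 genes, median 0.25, adjusted p = 0.0167; 0.571 with an estimated correlation, as for the next 3 lists), led by Calr, Tap2, Psmb9 and Tapbp at 0.26 to 0.45. So was the reference gene list (15 of 19, median 0.15, adjusted p = 0.0276), led by Ppia, Gusb, Oaz1 and Sf3a3. The monocyte and macrophage markers were lower in 21 of 22 genes (median -1.0, adjusted p = 0.000246), among them Vcam1, Sirpa and Timd4. So were the neutrophil and granulocyte markers in 16 of 16 (median -1.05, adjusted p = 0.0356; Csf3r, Mmp9, Fpr1 and Chil3). None of these 6 lists passed with fry (adjusted p = 0.163 to 0.354). With reference gene normalization the neutrophil and granulocyte list (camera adjusted p = 0.183) and the reference gene list (0.122) were not called. For the reference gene list this tests nothing, since its 19 genes set that scaling. Without Control replicate 1, 2 lists were called, and without the 5 shallow libraries and Control replicate 3 only the monocyte and macrophage list was (0.00724). edgeR called 0 genes with 82 at an unadjusted p under 0.05 (chance 26.4). DESeq2 and limma after quantile normalization called 0, and limma with sample weights called 1, Emp1 (0.0134). The groups did not overlap for 52 genes (9.85%, chance 2.86%). Tnfsf10 was higher adjusted over the cytotoxic list alone.

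At day 8 the 3 treatments were compared in the same way. With VIP-KO pDC the neutrophil granule genes Ctsg, Mpo and Elane, which encode a protease, a peroxidase and an elastase, averaged 119 ± 76.2, 267 ± 201 and 91.9 ± 95.03 CPM (n = 4), against 12.9 ± 3.34, 36.5 ± 24.8 and 15.2 ± 7.86 with WT pDC (n = 4). The log2 fold changes were 3.20 ± 0.77, 3.00 ± 0.78 and 2.83 ± 0.85 and did not pass (edgeR adjusted p = 0.19, 0.21 and 0.493), and the 3 genes were above background in only 1 of 4 VIP-KO libraries, replicate 3. The neutrophil and granulocyte list was higher in 11 of 16 genes (median 0.18, camera adjusted p = 0.00714; adjusted p = 0.745 with an estimated correlation), and these 3 genes passed adjusted over the list alone. The monocyte and macrophage list was higher in 18 of 22 genes (median 0.62, adjusted p = 0.00714; 0.745 with an estimated correlation). It was led by Vcam1 (1.08 ± 0.57), Cd163 (1.61 ± 0.86), the complement gene C1qa (1.11 ± 0.63) and Fcgr1 (1.30 ± 0.76). Without the 5 shallow libraries this list turned to lower (adjusted p = 0.0284). The neutrophil and granulocyte list was then lower in 11 of 16 genes (median -0.84) and not called (camera adjusted p = 0.152). With all libraries the cytotoxic list was lower in 6 of 6 genes (median -0.15, adjusted p = 0.0375, and 0.745 with an estimated correlation). In it Tnfsf10 was at -0.26, the granzyme gene Gzma at -0.30, Nkg7 at -0.21 and the granzyme inhibitor gene Serpinb9 at -0.08.

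edgeR called 0 of 528 genes in VIP-KO against WT at day 8, with 8 at an unadjusted p under 0.05 where chance gives 26.4. limma called 0 after quantile normalization and 0 with sample weights, and DESeq2 called 2, Ctsg (adjusted p = 0.011) and Mpo (0.0204). Without VIP-KO replicate 4, edgeR called 3, Mpo and Ctsg (0.00467 each) and Elane (0.0112). That fit left out a deep library (1304285 counts) and kept the shallow VIP-KO replicates 1 and 2. The groups did not overlap for 4 genes (0.758%, chance 2.86%). Without VIP-KO replicate 2 or WT replicate 2 none of the 3 lists was called.

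Between WT and Control at day 8 no gene passed with edgeR (0 called, 11 at an unadjusted p under 0.05 where chance gives 26.4, smallest adjusted p 0.999). DESeq2 called 0, and limma called 0 after quantile normalization and 0 with sample weights. The collagenase gene Mmp8 of neutrophils (2.40 ± 0.82), the fatty acid receptor gene Cd36 (-2.66 ± 0.93) and the adhesion gene Alcam (-0.30 ± 0.11) had the smallest p-values. The neutrophil and granulocyte list was higher with WT pDC in 14 of 16 genes (median 0.59, camera adjusted p = 0.000209, and 0.966 with an estimated correlation). It included S100a8 at 2.28 ± 0.91, Camp at 2.15 ± 0.86 and S100a9 at 2.06 ± 0.87. Camp was at 163 CPM in WT replicate 1 and at 9.81 to 31.5 in the other WT libraries. No Control library was above background for Camp. The immediate early and cAMP response list was higher in 14 of 17 (median 0.08, adjusted p = 0.00258; 0.89 with an estimated correlation), with the phosphatase genes Dusp1 (0.54 ± 0.33) and Dusp6 (0.13 ± 0.11), Rgs1 (0.27 ± 0.19) and Nr4a2 (0.31 ± 0.24). Neither list was called without WT replicate 3, Control replicate 1 or Control replicate 4, and 4 lists were called without Control replicate 2. The groups did not overlap for 9 genes (1.7%, chance 2.86%).

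VIP-KO against Control at day 8 gave 0 genes with edgeR (11 at an unadjusted p under 0.05), 0 with DESeq2, and 0 with limma after quantile normalization or with sample weights. Mpo, Ctsg and Elane again had the smallest p-values, with log2 fold changes of 2.85 ± 0.80, 2.85 ± 0.80 and 3.02 ± 0.90 (adjusted p = 0.435, 0.435 and 0.473). These 3 genes passed without VIP-KO replicate 4 (edgeR adjusted p = 0.0112 for Mpo, 0.0157 for Elane and 0.0164 for Ctsg). Ctsg passed without Control replicate 2 (0.0237). VIP-KO replicate 4 was a deep library (1304285 counts). Without it the group held the shallow replicates 1 and 2 (15.0 and 23.2% background) and replicate 3. Only in replicate 3 of VIP-KO were these 3 genes above background. The neutrophil and granulocyte list was higher in 15 of 16 genes (median 1.23, camera adjusted p = 1.92e-08; adjusted p = 0.77 with an estimated correlation). Of its genes 5 passed adjusted over the list alone, against 0 over all genes, and Chil3, a chitinase-like gene, was at 2.71 ± 0.87. These values include the shallow VIP-KO replicates 1 and 2 and the shallow Control replicate 2. Against WT at day 8 the same list was lower in 11 of 16 genes without the 5 shallow libraries (median -0.84). The cytotoxic list (median -0.21, 6 of 6 lower) and the class I list (median -0.17, 12 of 12 lower; H2-M3, H2-Q10, Tapbp and Calr at -0.22 to -0.32) were lower at an adjusted p = 0.0264 each. The estimated correlation gave them an adjusted p of 0.77 and 0.783. Without VIP-KO replicate 2 or Control replicate 1, 1 list was called, and 5 were called without VIP-KO replicate 1 or VIP-KO replicate 3. The groups did not overlap for 5 genes (0.947%, chance 2.86%).

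The change from day 8 to day 15 was compared within each treatment. Cd244a, a receptor of cytotoxic and exhausted T cells, rose from 250 ± 45.4 to 902 ± 108 CPM in Control (n = 4 each; log2 fold change 1.89 ± 0.15, edgeR adjusted p = 2.58e-09). In the same units it rose from 274 ± 24.3 to 1129 ± 176 with WT pDC (2.06 ± 0.15, 1.89e-10) and from 258 ± 35.8 to 910 ± 128 with VIP-KO pDC (1.87 ± 0.16, 7.11e-09). Itgax, the gene of the integrin CD11c, fell from 414 ± 85.5 to 150 ± 62.7 in Control (-1.73 ± 0.24, 1.65e-05). It fell from 390 ± 61.3 to 93.0 ± 12.6 with WT pDC (-2.09 ± 0.24, 5e-07) and from 368 ± 126 to 123 ± 34.4 with VIP-KO pDC (-1.61 ± 0.23, 2.65e-05). H2-Q10, a class I gene, fell as far (-1.79 in Control, -1.99 with WT pDC and -1.55 with VIP-KO pDC). Cd80, a costimulatory ligand gene, and Nfil3 rose in all 3 treatments. The rise of Cd80 in Control was 1.20 ± 0.16 (log2), and that of Nfil3 was 0.83 ± 0.12 in Control and 1.18 ± 0.12 with WT pDC.

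edgeR called 110 genes for day in Control (60 higher and 50 lower at day 15), 95 with WT pDC (55 and 40) and 96 with VIP-KO pDC (54 and 42). Genes called in all 3 treatments numbered 30 higher (0.639 would be shared by independent draws) and 19 lower (0.301). Besides those above, the shared rises included the chemokine gene Ccl3, Spry2, Nr4a2, Pdgfb and the checkpoint ligand gene Cd274, all chosen after their values were seen. The shared falls, chosen in the same way, included the T cell exit and homing genes S1pr1, Itgb7 and Gpr183, and Gzma and Serpinb9. The 4 libraries of the days did not overlap for 92 of the 528 genes in Control (17.4%), 182 with WT pDC (34.5%) and 133 with VIP-KO pDC (25.2%), where chance gives 2.86%. Of the called genes 67 of 110, 92 of 95 and 83 of 96 did not overlap. Scaling to the reference genes in place of TMM raised the median log2 fold change of all genes by 0.28 in Control, 0.23 with WT pDC and 0.13 with VIP-KO pDC. It called, in that order, 112 higher and 23 lower, 115 and 23, and 112 and 31. Of the falls called with TMM scaling 23, 23 and 30 were called lower with reference scaling too, and none of the calls changed sign. With quantile normalization 2 of the 110 in Control did, and its median shifts were -0.31 in Control, -0.10 with WT pDC and 0.06 with VIP-KO pDC.

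**Figure D3:**
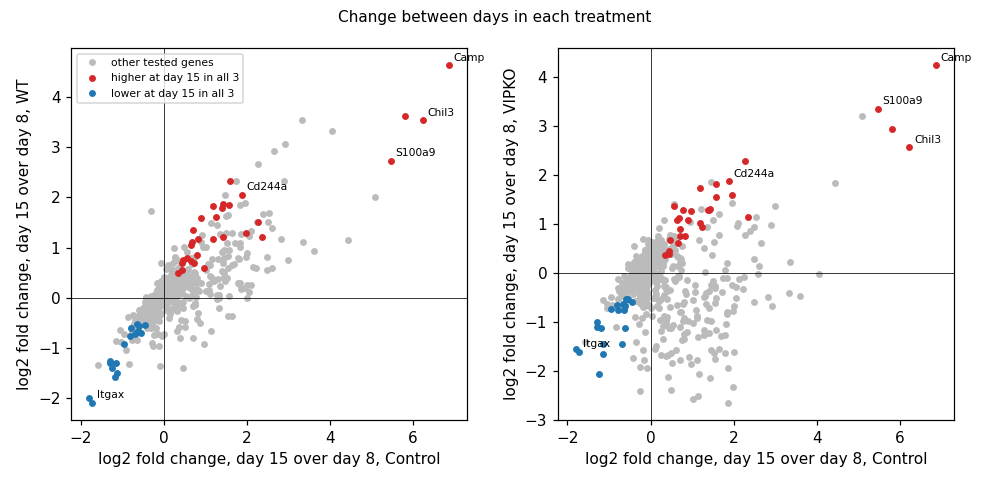
Log2 fold change from day 8 to day 15 with WT pDC (left) and VIP-KO pDC (right) against that in Control, for 528 genes; red and blue points are the 30 genes higher and the 19 genes lower at day 15 in all 3 treatments, by TMM scaling. Camp is at 6.86 in Control, from day 8 values near background.

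The largest rises were in genes of neutrophils and their precursors. In Control, Camp, an antimicrobial peptide gene, rose from 20.3 ± 13.3 to 1681 ± 1272 CPM (n = 4 each; log2 fold change 6.86 ± 0.81, edgeR adjusted p = 1.88e-06), and Chil3, Chil4, S100a9, S100a8, Mmp8, Elane, Alox5, Alox5ap and Mpo rose by 3.33 to 6.23. With WT pDC, Camp rose by 4.63 ± 0.66 (1.18e-05), Chil4, Mpo, Chil3, Elane, Ctsg, S100a9 and Fcnb rose by 2.66 to 3.61, and the B cell gene Ms4a1 and the collagen receptor gene Mrc2 rose by 2.92 and 2.33. With VIP-KO pDC, Camp rose by 4.24 ± 0.72 (0.000125), S100a9, S100a8, Chil4 and Chil3 by 2.56 to 3.34, and the class II gene H2-Ab1 (2.27), Cd244a, Sema6d (1.86), Ccrl2 (1.81) and Ccl3 (1.74) made up the rest of the 10 largest. At day 8 Camp, Chil3 and Chil4 were above background in 0 of 4 Control libraries, 1 of 4 with WT pDC and 1 of 4 with VIP-KO pDC, so these fold changes rest on day 8 values near background. With background subtracted the fitted rises in Control were 9.49 for Camp and 12.83 for Chil3, so their sizes and order depend on how background is handled.

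**Figure D4:**
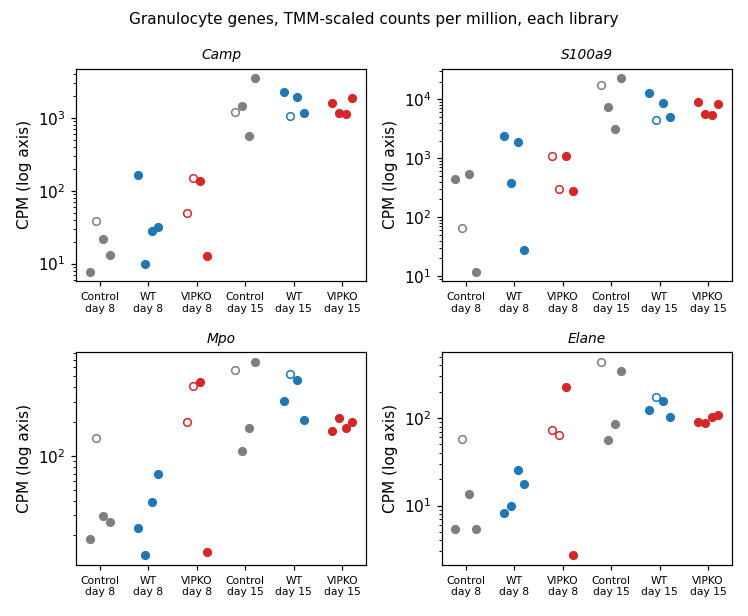
TMM-scaled counts (CPM, log axis) of the neutrophil genes Camp, S100a9, Mpo and Elane in each library by treatment and day; points are libraries, with open circles for the 5 libraries under 150000 counts. Camp averages 20.3 CPM in Control at day 8 and 1681 at day 15.

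Besides Itgax and H2-Q10, the largest falls in Control were Jun, Serpinb9, Itgb7, Cd99, Gzma, H2ac18, S1pr1 and Gpr183 (-1.13 to -1.59). With WT pDC they were Gzma, Gpr183, Cd99, the gut homing receptor gene Ccr9, S1pr1, Serpinb9, Itgb7 and Ccr2 (-1.04 to -1.58). With VIP-KO pDC they were Nectin1, Vcam1, Cd99, Mapk11, the complement gene C1qb, Gpr183, Rasal1 and S1pr1 (-1.46 to -2.42), in the group whose day 8 replicates 1 and 2 were shallow. Nectin1 was above background in 2 of 4 libraries at day 8 and 0 of 4 at day 15. Ifng, the gene of interferon gamma, fell in Control from 1792 ± 518 to 804 ± 301 CPM (-1.05 ± 0.26, edgeR adjusted p = 0.00528), and did not pass with WT pDC (-0.64, 0.0791) or VIP-KO pDC (-0.71, 0.0518). Tnf fell with VIP-KO pDC from 326 ± 89.2 to 202 ± 23.5 CPM (-0.59 ± 0.21, 0.0477) and did not pass in Control or with WT pDC. The VIP-KO day 8 mean includes the shallow replicates 1 and 2, with 15.0 and 23.2% background. The Control day 15 mean includes 606 CPM in the shallow replicate 1, against 214 to 273 in the others.

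In Control 6 lists were called for day. The neutrophil and granulocyte list was higher with 12 of 16 genes called (14 adjusted over the list alone; median 2.76, camera adjusted p = 3.49e-08; adjusted p = 0.465 with an estimated correlation). The class II antigen presentation list was higher with 5 of 12 genes called (7 over the list alone; median 1.28, 0.00311; 0.397 with an estimated correlation), led by Cd80, H2-Ab1, Cd74 and H2-Aa. Markers of other cells that carry class II were not called as lists. B cell markers were higher in 4 of 4 genes (median 1.08) and monocyte and macrophage markers in 17 of 22 (median 0.41). Without the 5 shallow libraries and Control day 15 replicate 3 these medians were 1.09 and -0.004. The monocyte and macrophage rise thus depended on those libraries. The class I list was lower with 3 of 12 called (4 over the list alone; median -0.42, 0.00311; 0.617 with an estimated correlation), H2-Q10, H2-T23 and Psmb9, with H2-M3 not passing. Cell cycle and proliferation was lower with 2 of 7 called, Mcm5 (-0.61) and Cdc20 (-0.54) (3 over the list alone; median -0.48, 0.0468; 0.617 with an estimated correlation), while Birc5 and Ccnb2 did not pass. The reference genes were lower with 5 of 19 called (6 over the list alone), led by G6pdx, Tubb5, Polr2a and Oaz1. Their median was -0.18 (camera adjusted p = 0.00356, and 0.617 with an estimated correlation). It was 0.09 with reference scaling, which no longer called the list. That scaling is set by these same 19 genes, so the lost call was largely fixed in advance and tests nothing about them. T cell identity and signalling was lower (median -0.32, 0.0217; 0.658 with an estimated correlation), while Nfatc1, Nfatc2 and Ccr7 did not pass. Its median was -0.04 with reference scaling, which no longer called it. Without Control day 15 replicate 1, 3 lists were called in place of 6.

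With WT pDC 3 lists were called for day. The class II list was higher with 5 of 12 genes called (7 over the list alone; median 1.18, camera adjusted p = 0.00822; adjusted p = 0.504 with an estimated correlation), led by Cd80, the protease gene Ctss (0.48), Cd74 (1.63) and H2-Aa (1.88). B cell markers were higher in 3 of 4 genes (median 0.82) and monocyte and macrophage markers in 13 of 22 (median 0.17), neither called. Without the 5 shallow libraries and Control day 15 replicate 3 these medians were 0.60 and -0.12. The neutrophil and granulocyte list was higher with 6 of 16 called (6 over the list alone; median 1.41, 0.00042; 0.626 with an estimated correlation). The reference genes were lower with 5 of 19 called (5 over the list alone; 0.0391; 0.791 with an estimated correlation), led by G6pdx, Tubb5, Hprt and Polr2a. Their median of -0.15 turned to 0.08 with reference scaling, which no longer called the list. Since these 19 genes set that scaling, the lost call tests nothing about them. With VIP-KO pDC camera called 0 lists (smallest adjusted p 0.191, for the monocyte and macrophage list), although 4 of 16 granulocyte genes and 2 of 12 class II genes passed on their own. Without VIP-KO day 8 replicate 2, 2 lists were called, without replicate 3 of that group 1, and without the 5 shallow libraries 3.

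Whether the treatments differed in their change over time was tested directly. No gene passed with edgeR for VIP-KO against WT (0 called, 22 at an unadjusted p under 0.05, smallest adjusted p 0.285; DESeq2 0) or for WT against Control (0, 23 and 0.973; DESeq2 0). For VIP-KO against Control edgeR also called 0 (82 at an unadjusted p under 0.05, smallest adjusted p 0.234), and DESeq2 called 1, Alox5 (0.019). limma after quantile normalization called 0 in each. For VIP-KO against WT the smallest p-values were those of Mpo, Ctsg and Elane, with differences in log2 fold change of -3.96 ± 1.01, -3.75 ± 1.01 and -3.33 ± 1.11. For WT against Control the smallest p-values were those of Mmp8 (-3.28), Emp1 (-0.84) and Ccr9 (-1.85), and for VIP-KO against Control those of the leukotriene gene Alox5 (-4.09), Mpo (-3.74) and Chil3 (-3.67). Without VIP-KO day 8 replicate 4, Mpo (edgeR adjusted p = 0.00502), Ctsg (0.0194) and Elane (0.0393) passed against WT. Against Control 5 genes then passed, Mpo and Elane (0.0123 each) and Chil3, Ctsg and Alox5 (0.0213 each). Replicate 4 was a deep library (1304285 counts), and its removal left the shallow replicates 1 and 2 with replicate 3. Only in replicate 3 of that group were Mpo, Ctsg and Elane above background. Without Control day 8 replicate 2, Ctsg passed against Control (0.0437).

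Of the T cell genes named in advance, Vip, its receptor genes Vipr1 and Vipr2, Ifng, Tnf, Il2, Il4, Il10, Gata3, Pdcd1 and Ctla4 were tested, and none passed with edgeR in any comparison of treatments. limma with sample weights called Il10 (-0.72, adjusted p = 0.0176) and Gata3 (-0.25, 0.0452) lower in VIP-KO against WT at day 15. Raw Vip counts were 8 to 45 in the 24 libraries, at the level of the negative control probes in most of them. Ifng averaged 1231 ± 106 CPM with WT pDC, 1147 ± 98.0 with VIP-KO pDC and 804 ± 301 in Control at day 15, and Pdcd1, the gene of the checkpoint receptor PD-1, averaged 6652 ± 402, 6388 ± 959 and 4569 ± 1686 (n = 4 each). WT against Control gave edgeR adjusted p-values of 0.657 for each of these. Gata3, the Th2 transcription factor gene, averaged 840 ± 56.5 with VIP-KO pDC and 975 ± 69.4 with WT pDC at day 15 (edgeR adjusted p = 0.9), and Ctla4 averaged 1120 ± 145 and 1038 ± 107 (0.991). Il17a, Foxp3, Tbx21, Gzmb, Prf1, Fasl, Il2ra, Cd4, Cd8a and Cd3e were not analysed here. Of the lists, T cell activation and checkpoint, Th1, Th17, regulatory T cell, interferon response, chemokine ligands, chemokine receptors and homing, apoptosis, Toll-like receptor and NF-kB, growth factor and TGF-beta signalling, B cell and dendritic cell markers were not called by camera in the 9 pairwise comparisons of groups with all libraries and the filter on low counts. fry called 4 of them: Toll-like receptor and NF-kB lower in VIP-KO against Control at day 15 (adjusted p = 0.0437), chemokine ligands (0.012 and 0.0165) and growth factor and TGF-beta signalling (0.0181 and 0.00296) higher at day 15 in Control and with WT pDC, and dendritic cell markers lower at day 15 with WT pDC (0.0165).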

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

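The tests of explanations in this part, and the fits without 5 or 6 libraries, were chosen only after the results were seen. A value was singled out where 1 library of the 4 in a group lay far from the others by Dixon's test, which chance does in about 1 in 20 groups. Of 180 groups checked 23 did so, and over the 101 genes named 77 of 606 groups (12.7%) did, 65 of them because of a shallow library.

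Control day 8 replicate 2, with 95479 counts, stood out most. It had 316 endogenous probes at 20 counts or more, against 469 to 488 in the other Control libraries of that day. Its Vip (143 CPM), Vipr1 (153), Vipr2 (124), Mpo (143), Ctsg (76.4), Chil3 (57.3) and Elane (57.3) were the highest of the group, and its Itgax (287) was the lowest. WT day 15 replicate 2 had 345 probes at 20 counts or more, against 493 to 514, and the highest Vip (220), Vipr1 (101) and Vipr2 (156) of its group. Control day 15 replicate 1, with 18250 counts, had the highest Vip (606), Vipr1 (236), Vipr2 (269), Tnf (606), Il2 (236) and Il10 (404) of its group. Among deeper libraries, WT day 8 replicate 1 had the highest Ifng (2806, others 1616 to 1637) and Camp (163, others 9.81 to 31.5), WT day 8 replicate 3 the highest Vipr1 (70.1), and VIP-KO day 15 replicate 2 the highest Nr4a2 (2441, others 1830 to 1931). No cause was tested for these.

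Probes left out of the tests gave a signal in Control day 15 replicate 3, where 165 of 234 reached the background limit, against 0 to 12 in the other libraries. Its cause was not tested. It is the library left out together with the 5 shallow ones in the fits without 6 libraries.

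At day 8 the monocyte and macrophage list and the neutrophil and granulocyte list were higher with VIP-KO than with WT pDC, while 2 of the 4 VIP-KO libraries were shallow and none of the WT libraries of that day was. Background counts of the shallow libraries are a candidate explanation for the marker monocyte and macrophage list: without these libraries it turned to lower (adjusted p = 0.0284; 0.000115 to 0.935 over its alternatives). RNA from granulocytes in the VIP-KO libraries cannot be told apart from background, since the marker neutrophil and granulocyte list was not called without the shallow libraries and had 11 of 16 genes lower there (median -0.84, adjusted p = 0.152; 2.26e-05 to 0.863 over its alternatives). A lost call had been written as excluding this explanation, but only 2 VIP-KO libraries were left, and in 1 of them, replicate 3 with 1410644 counts, Ctsg, Mpo and Elane had 230, 540 and 274 counts, above its background limit. A response of T cells to VIP-KO pDC remains open and untested.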

How the results depend on the processing

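Leaving out the 5 shallow libraries or 6 libraries, subtracting background, and the replicate block in a fit of only 2 groups were chosen after seeing the data. No called value of a gene named changed sign under any alternative. The gene counts between treatments stayed as reported, at 0 or at 1 for WT against Control at day 15, under every alternative not listed for them here, and the day counts stayed within 1.5 times of 110, 95 and 96. The cause of a change was not tested unless given.

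VIP-KO against WT at day 8 went from 0 genes to 2 with DESeq2 (Ctsg and Mpo), 1 with no filter on low counts (Ctsg) and 2 with background subtracted (Cd180 and Mpo). WT against Control at day 8 went from 0 to 1 with background subtracted (Cd180). VIP-KO against WT at day 15 went from 0 to 41 with sample weights, and VIP-KO against Control from 0 to 1 (Emp1). For the change over time VIP-KO against WT went to 2 with background subtracted (Mpo and Cd180), WT against Control to 1 without the 6 libraries (Irf4, log2 0.74), and VIP-KO against Control to 1 with DESeq2 (Alox5). The genes in brackets were chosen after their values were seen.

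WT against Control at day 15 went from 1 gene to 8 with DESeq2, 2 with quantile normalization (Ccl4 and Ccl3, not Nfil3), 8 with at least 50 counts in 12 libraries, 7 with a pseudocount of 10, 25 with sample weights, 10 without the 5 shallow libraries, 5 without the 6 libraries and 5 with background subtracted. It fell to 0 with no filter (25 at an unadjusted p under 0.05) and with only the groups compared (24). Reference gene normalization gave 1 gene, Ccl4 in place of Nfil3. Over the alternatives the adjusted p of Nfil3 ran from 7.23e-05 to 0.496, and its log2 fold change stayed positive.

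The day counts in Control, WT and VIP-KO went to 54, 41 and 47 with no filter, of which 52, 40 and 44 were shared with the reported calls, to 237, 218 and 198 with sample weights, and to 225, 173 and 217 without the 5 shallow libraries (108, 95 and 90 shared). WT and VIP-KO gave 175 and 215 without the 6 libraries. Fits of only the groups compared gave 44 in Control and 194 in WT, limma without the variance trend gave 62 in WT, and at least 50 counts in 12 libraries gave 145 in VIP-KO. A fold change of at least 1.5 left 90, 76 and 78.

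Reference gene scaling moved the median of all genes by -0.14 in VIP-KO against Control at day 15 and by -0.15 in its change over time. Quantile normalization moved it by 0.16 in WT against Control and 0.24 in VIP-KO against Control at day 15, and by 0.12, 0.14 and 0.36 in the changes over time.

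Lists called went to 0 with an estimated correlation in each of the 8 comparisons that had any. With fry they went to 0 in VIP-KO against WT, WT against Control and VIP-KO against Control at day 8 and in VIP-KO against WT and WT against Control at day 15, and in VIP-KO against Control at day 15 none of the 6 was called and 1 other list was (Toll-like receptor and NF-kB). For the days in WT fry called 5 in place of 3, of which 2 were shared, and in Control 5 in place of 6, of which 3 were shared: class I (fry adjusted p = 0.0785), cell cycle (0.0785) and T cell identity (0.101) were lost. With no filter, which adds genes to the lists, they went from 3 to 11, 3 to 7, 1 to 8, 2 to 11 and 6 to 13 in VIP-KO against WT and against Control at day 8 and VIP-KO against WT, WT against Control and VIP-KO against Control at day 15, and to 10 and 4 for the days in Control and VIP-KO. With background subtracted they went to 0 in VIP-KO against WT at day 8, 1 in WT against Control and 2 in VIP-KO against Control at day 15, and 4 for the days in VIP-KO. Without the 5 shallow or the 6 libraries they went to 4 in WT against Control at day 8, 0 in WT against Control at day 15 and 3 for the days in VIP-KO, and without the 6 also to 1 in VIP-KO against Control at day 15.

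Leaving out each library in turn gave 0 to 3, 0 to 0 and 0 to 3 genes at day 8 (VIP-KO against WT, WT against Control, VIP-KO against Control), 0 to 0, 0 to 4 and 0 to 0 at day 15, 83 to 143, 69 to 88 and 75 to 106 for the days in Control, WT and VIP-KO, and 0 to 3, 0 to 0 and 0 to 5 for the changes over time. Genes between treatments appeared at day 8 without VIP-KO replicate 4 (3 and 3) or Control replicate 2 (1, against VIP-KO), and so did those of the changes over time (3 and 5, and 1). WT against Control at day 15 gave 0 without WT replicate 1 or 4 or Control replicate 2, 3 without WT replicate 2, and 4 without Control replicate 3 or 4. The lists ran 0 to 4, 0 to 4 and 1 to 5 at day 8, 0 to 3, 0 to 3 and 2 to 7 at day 15, and 3 to 6, 2 to 3 and 0 to 2 for the days. Lists at day 8 fell to 0 without VIP-KO replicate 2 or WT replicate 2 (VIP-KO against WT), to 0 without WT replicate 3 or Control replicate 1 or 4 (WT against Control) and to 1 without VIP-KO replicate 2 or Control replicate 1 (VIP-KO against Control). They rose to 4 without Control replicate 2 (WT against Control) and to 5 without VIP-KO replicate 1 or 3 (VIP-KO against Control). At day 15 VIP-KO against WT gave 0 without WT replicate 1, 2 without WT replicate 4 and 3 without VIP-KO replicate 4 or WT replicate 3. WT against Control gave 1 without WT replicate 3 or 4 and 0 without Control replicate 1, whose removal also left 2 in VIP-KO against Control and 3 for the days in Control. For the days in VIP-KO 2 lists were called without day 8 replicate 2 and 1 without replicate 3. Of the values of genes named, leaving out a library kept 2537, took 87 out of the calls, brought 20 in and turned the sign of 124 that were not called.

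A replicate block in the fit of all groups gave 1 gene in WT against Control at day 15 and 106, 97 and 92 for the days, with 0 genes elsewhere and the same counts of lists. In VIP-KO against WT at day 15, whose libraries deviate together by number, a replicate block in a fit of only these 8 libraries gave 17 genes in place of 0 and 4 lists in place of 1, that 1 (cell cycle) among them. Of the 8 splits that part all 4 pairs only the real one gave 17 genes (highest other 0), and 2 gave as many lists (highest other 5); 8 splits are too few for a share under 5%. In the other 5 pairs of groups of a day the correlations of the same number ran from -0.694 to 0.7 and did not all pass 0.1, so the numbers were not taken to pair those samples. Over the 24 libraries 5 correlated best with their own number.

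Depth limits the genes near background. The shallow libraries read such genes as high CPM values.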

Other observations

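The tests of explanations, except the splits and the tests of WT along the change over time, and the fits without 5 or 6 libraries, with background subtracted or with a replicate block in 2 groups, were chosen only after the results were seen.

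At day 15 limma with sample weights called genes that the main comparison of VIP-KO with WT did not. Lower with VIP-KO pDC were Pdgfb (log2 fold change -0.74 ± 0.13, adjusted p = 0.00459; 0.00459 to 0.997 over its alternatives; all 4 libraries below all 4 of WT), Spry2 (-0.70), Ccl4 (-0.58), Ccl3 (-0.57), Ccl5 (-0.48), Nr4a2 (-0.61), Nfil3 (-0.40) and Il10 (-0.72). Higher were Csf1, a macrophage growth factor gene (0.87), Cd81 (0.53), the death receptor gene Fas (0.53), the mitotic genes Kif20a (0.56) and Ndc80 (0.46), Mcm5 (0.33) and Birc5 (0.44). The lowest weights were those of Control day 15 replicate 1 (0.0414), VIP-KO day 8 replicate 2 (0.0692), Control day 8 replicate 2 (0.185), VIP-KO day 8 replicate 1 (0.211) and WT day 15 replicate 2 (0.378), the 5 shallow libraries. The genes were chosen after their values were seen, and edgeR called 0 genes here without the shallow libraries too (70 at an unadjusted p under 0.05). A paired fit of only these 8 libraries (a replicate block) called 17 genes, of which Spry2, Pdgfb, Nfil3, Ccl3, Ccl4 and Kif20a are among those above.

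WT at day 15 stood apart from Control in Nfil3 and, without the shallow libraries, in Emp1, Ccl4, Tnfrsf1a, Nr4a2, Irf4, Ccl3, Stat3, Pdcd1lg2 and Ccrl2. Counting noise of shallow libraries is argued against for Nfil3 alone, called with all libraries and without the shallow ones (adjusted p = 0.0155; 7.23e-05 to 0.496 over its alternatives); the other 9 of the 10 genes were picked by that fit and test nothing. Background counts are argued against for Nfil3 alone too, which stayed called when background was subtracted (0.65 ± 0.12 before, 0.72 ± 0.16 after, adjusted p = 0.0149), while the median of the 10 genes (113% of its size) decides nothing for the others. More granulocyte RNA with WT pDC would raise the granulocyte list, but its median was -0.66 without the 6 libraries, with 0 of 16 genes above 0. That fit left only replicates 2 and 4 of Control at day 15. The median was -0.79 with all libraries, among them Control replicate 1, in which background made up 60.5% of the signal. The explanation is argued against only within these limits. A response of T cells to WT pDC stays open, and so does chance, since 3 of 35 splits gave as many genes as the real 1 (highest other 3).

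A hypothesis was that T cells with WT pDC had gone further along the change from day 8 to day 15 than those of the other groups. Of the 110 genes called for day in Control, 81 (73.6%; 45 of 60 rises and 36 of 50 falls) differed in the direction of the day between WT and VIP-KO at day 15, and 4 of 35 splits of those libraries gave as large a share (highest other 75.5%), as did 2 of the 8 that part all same-numbered libraries (highest other 74.5%). Of the 96 called for day with VIP-KO pDC, 72 (75%; 41 of 54 and 31 of 42) did so between WT and Control, and 3 of 35 splits gave as large a share (highest other 75%). Both missed the bound of under 5% of splits set before the test. A miss had been written as excluding the hypothesis, but a share of 73.6% or 75% that 3 or 4 of 35 splits reach does not show that the groups were level, so the hypothesis cannot be told apart from chance.

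The rise of granulocyte genes at day 15 may reflect RNA from granulocytes among the sorted cells. Background counts of shallow libraries are argued against in Control, where 12 of the 12 list members called (100%) were still called without the 6 libraries. Those 12 were picked by a fit that includes the libraries kept, and only replicates 2 and 4 of Control at day 15 were kept. The same count was not made with WT or VIP-KO pDC. A lower share of T cells with more of every other cell type is argued against in 3 of 3 treatments without the 6 libraries: the lower quartile of the granulocyte list lay above the upper quartile of the macrophage list, with medians of 3.38, 1.37 and 1.54 against -0.00, -0.12 and 0.02 in Control, WT and VIP-KO, although the 4 B cell genes rose too (1.09, 0.60 and 1.07). This test replaced a first one, a macrophage median of 0 or lower with all libraries, which was met in 1 of 3 treatments and decided nothing. RNA from granulocytes needs its 16 genes to vary together between libraries of a group. Their mean pairwise correlation over 18 libraries was 0.455, above the 0.124 that 95% of 10000 random lists stay under (median 0.0415). No other marker list was scored in this way, and depth still differed within groups (293306 to 1321448 counts in WT at day 8). The correlation therefore does not single out RNA from granulocytes. A sort for T cells should remove granulocytes; S100a9 averaged 7124 to 12607 CPM and Camp 1455 to 1681 CPM at day 15, and expression by T cells was not tested.

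For the genes called for day, 1 of 35 splits of the 8 libraries, the real one, called as many in each treatment. The counts were 110 in Control (highest other 65), 95 with WT pDC (highest other 0) and 96 with VIP-KO pDC (highest other 10). This argues against a chance split of these libraries, at the smallest share that 35 splits allow. It does not exclude chance between mice, since the samples of a group may not be separate mice. The other splits mix the days. For the counts of genes between treatments that were 0 the splits say nothing about chance, since any split reaches 0. All 35 did in VIP-KO against WT (highest other 27), WT against Control (2) and VIP-KO against Control (69) at day 8, and in VIP-KO against WT (0) and VIP-KO against Control (0) at day 15. The split with 69 genes put VIP-KO replicates 1 and 2 and Control replicates 2 and 4 on 1 side, which joins the 3 shallow libraries of those groups and points to depth as a structure of the samples. The split with 27 genes also joined VIP-KO replicates 1 and 2. The same holds for the 100 splits drawn for the change over time, all of which reach the real 0 (highest other 1 for VIP-KO against WT, 3 for WT against Control and 60 for VIP-KO against Control, which again points to a structure of the samples).

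For lists chance could not be excluded in the 8 comparisons that called any. Splits with several times the real count may come from a structure of the samples. They may also come from the preset correlation of 0.01, since the granulocyte list had a mean pairwise correlation of 0.455 within groups. These were not told apart. At day 8, 21 of 35 splits gave as many lists as the real 3 in VIP-KO against WT (highest other 8), 26 as many as the real 2 in WT against Control (7) and 25 as many as the real 3 in VIP-KO against Control (7). At day 15 it was 25 for the real 1 in VIP-KO against WT (4), 28 for the real 2 in WT against Control (7) and 4 for the real 6 in VIP-KO against Control (7). For the days it was 13 for the real 6 in Control (8) and 13 for the real 3 with WT pDC (9). The real 0 with VIP-KO pDC is reached by all 35 (highest other 10), which tests nothing.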
